A study of Mus musculus with 4 samples.

How the data were processed

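RNA was measured per barcode in LSK cells (lineage-negative, Sca-1-positive, Kit-positive blood progenitors). They were sorted from mouse fetal liver at embryonic day 14.5 and from bone marrow at 8 weeks, each from wild-type and from Thpo-knockout mice. The 4 libraries were made with the 10x Genomics Chromium multiome kit for chromatin and gene expression, per the labels' protocols, and the gene expression part was used. Each group is 1 library. The deposited values are raw UMI counts per gene and barcode. Cell Ranger made them on the mouse build mm10 and filtered the barcodes, per the submitters' processing notes and the names of the deposited count matrices. The version of Cell Ranger and whether intronic reads were counted are not given in the sources used here. The values were checked to be whole numbers, with the lowest barcode total between 500 and 506 UMIs. The chromatin part of the kit was not analysed here.

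Barcodes are called cells below for short, and the design written before the data were examined called them nuclei. Cells with at least 500 genes were kept, and Scrublet calls were removed, at an expected doublet rate of 0.8% per 1000 barcodes. Scrublet made 52, 0, 2 and 4 calls in the wild-type fetal liver, knockout fetal liver, wild-type bone marrow and knockout bone marrow libraries. In the last 3 of these libraries the method therefore did not work, and doublets remain there. The design written before the data were examined also set a limit of 10% mitochondrial UMIs per cell. That limit was dropped after the data were seen, because it keeps 24.5%, 62.9%, 2.52% and 9.20% of cells in the libraries in the same order. The libraries hold median mitochondrial shares of 12.2%, 8.79%, 19.9% and 16.0%. Values under the preset limit are given as an alternative. Kept cells numbered 4367, 12295, 8281 and 6427, with 37327135, 40942304, 24779856 and 25701874 UMIs.

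Counts were summed over the kept cells of a library and divided by that sum, giving CPM (counts scaled to a common library total). Comparisons are log2 ratios of CPM with the exact conditional binomial (Clopper-Pearson) 95% interval. With 1 library per group there is no test of the conditions, no p-value and no count of changed genes, and every interval covers counting error only. A count of 0 was set to a floor of 3 counts in that library, and the ratio is then a bound. The comparisons were knockout against wild type in each tissue, fetal liver against bone marrow in each genotype, the difference of the knockout log2 ratios between stages (bone marrow minus fetal liver, untested, with intervals from 2000 Poisson redraws), and knockout against wild type within the stem cell-like cells of each tissue. Fetal liver and bone marrow differ in both age and tissue, and in wild type in sex as well, so these are one contrast.

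28 gene lists were fixed before the data were examined, and 1 of them and some single genes are not reported here. The others cover stem cell self-renewal and quiescence, megakaryocyte and platelet, erythroid, neutrophil and monocyte, lymphoid priming, and basophil, mast cell and eosinophil genes. Further lists cover DNA synthesis, mitosis, the fetal stem cell programme, the interferon response, oxidative phosphorylation, mitochondrial regulation, glycolysis and hypoxia, the p53 response, non-homologous end joining, and immediate early and stress genes. Lists of ribosomal proteins, sex-linked genes, globins, the mitochondrial genome and nuclear retained RNA, and markers of B lineage, T, NK and innate lymphoid, macrophage and dendritic, hepatocyte, endothelial and stromal cells complete the set. Some genes are in more than 1 list. A list member was measured with at least 50 UMIs over both libraries. The result of a list is the median log2 ratio of its measured members, an interval from 2000 Poisson redraws, and the percentile of that median among 10000 random lists of the same size matched in 20 bins of mean expression. A list is said to stand apart outside percentiles 2.5 to 97.5. Members at least 1.5-fold higher or lower with an interval excluding no difference were counted.

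Named genes follow a rule fixed before the data were examined, for the knockout comparisons, for wild-type fetal liver against bone marrow and for the stem cell-like cells. It takes Thpo, Socs2, Cish, Pim1, Bcl2l1 and Mcl1, among others, where they reach 50 UMIs. It takes the 10 highest and 10 lowest ratios among genes with at least 200 UMIs and at least 20 CPM in the higher library whose sign holds under the other scalings. Sex-linked genes, globins, mitochondrial genes, hepatocyte markers and unnamed gene models are left out of that part. It also takes up to 4 members of each list with the largest ratios among those with at least 200 UMIs, and the 5 genes each way whose knockout ratios differ most between stages with opposite signs. The text leaves out some members. Genes outside the rule are named as chosen after their values were seen. Gene identifiers and symbols are those of the deposited count matrices, and positions come from the GENCODE annotation of the same build.

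For cell classes the 2 libraries of a stage were clustered together without integration. The steps were 2000 variable genes without the cell cycle, sex-linked, globin and mitochondrial genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. A cluster took the name of 1 of 12 marker sets when at least 3 of the set's markers were 1.5-fold above the other clusters and found in at least 5% of its cells. The markers also had to average at least 1 on the log2 scale above the other clusters, or 2 of them, and no marker of another set, had to be among the cluster's top 10 genes. A cluster with more markers of another set among those genes stayed unnamed. This strength threshold was set after the clusters were seen, and the shares of the clusters it leaves unnamed are given. A ratio within the stem cell-like class was computed when both libraries held at least 100 such cells. Shares of cells carry exact (Clopper-Pearson) 95% intervals. Shares of cells with a UMI of a gene were counted after thinning every cell to 500 UMIs, the largest preset depth that enough cells of every library reached, and cell cycle phases were scored with scanpy on the same thinned counts.

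The step that computes ratios was tested on simulated data, drawn from the real means and library sizes with known changes. The draws were Poisson counts, as the intervals assume. The rates below therefore check the computation and hold no variation between cells, libraries or animals. In the simulated fetal liver knockout comparison, over 11853 genes, 100% of the 97 genes changed 2-fold and 100% of the 100 genes changed 1.5-fold had an interval excluding no difference, against 4.88% of unchanged genes. In the simulated bone marrow knockout comparison, over 10585 genes, these were 100% of 98, 99.0% of 100 and 4.71%. In the simulated wild-type stage comparison, over 11419 genes, they were 100% of 95, 98.0% of 99 and 4.78%, and in the knockout stage comparison, over 11478 genes, 100% of 94, 99.0% of 100 and 4.71%.

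Alternatives fixed before the data were examined were scaling by edgeR TMM factors, by DESeq2 size factors, and by totals without the most abundant genes. Others were equal weight for every cell, thinned cells, all barcodes, at least 1000 genes, doublets kept, clusters of mature, macrophage, hepatocyte, endothelial and stromal cells left out, no UMI floor with 0.5 added, a floor of 500 UMIs, resolutions 0.5 and 2, all 4 libraries clustered together, clustering on thinned cells, and knockout cells placed among wild-type clusters. Chosen after seeing the data were the 10% mitochondrial limit as an alternative, at least 2500 UMIs per cell, removal of the cells with the highest doublet scores, clustering without the stem cell genes, and thinning to 2000 UMIs. For these alternatives a gene ratio counts as called at 1.5-fold with an interval excluding no difference, and a list median as called when it also stands apart. A gene without counts in a library under equal cell weights takes the summed value at the floor.

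The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. It also used R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, both for scaling factors alone.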

Results

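The data are UMI counts per barcode from sorted LSK cells, the fraction of blood-forming tissue that holds stem cells and early progenitors. They came from wild-type mice and from mice lacking thrombopoietin (Thpo), a cytokine that acts on stem cells and on platelet-forming cells. Each of the 4 groups is 1 library, so there is no replicate check, and intervals cover counting error only. The wild-type fetal liver library gave 4367 kept cells with a median of 7705 UMIs, and the knockout fetal liver library 12295 cells with a median of 1518 UMIs. The wild-type bone marrow library gave 8281 cells with a median of 2559 UMIs, and the knockout bone marrow library 6427 cells with a median of 3538 UMIs. Cells under 2500 UMIs made up 3.14% and 62.4% of the wild-type and knockout fetal liver libraries, and 48.1% and 22.8% of the wild-type and knockout bone marrow libraries.

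Thpo gave 0 UMIs in the wild-type fetal liver library, 3 UMIs (exact 95% interval 0.619 to 8.77) in the knockout fetal liver library and 0 UMIs in both bone marrow libraries. The counts of 0 allow up to 0.080 CPM (counts scaled to library size) in wild-type fetal liver, 0.121 CPM in wild-type bone marrow and 0.117 CPM in knockout bone marrow. Thpo is made mainly by liver cells and other non-blood cells, and at these counts it checks no label. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together reached 308 CPM in the wild-type fetal liver library and 0.830, 0.323 and 0.661 CPM in the knockout fetal liver, wild-type bone marrow and knockout bone marrow libraries. Xist, the RNA of the silenced X chromosome, stood at 0.188, 947, 1457 and 1499 CPM in the same order. The wild-type fetal liver library was therefore male and the other 3 were female, and in fetal liver sex differs together with genotype.

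The fetal liver comparison asks what LSK cells look like when blood formation has begun without thrombopoietin. Stem cell genes were lower in the knockout library: the self-renewal and quiescence list had a median log2 ratio of −0.22 (95% interval −0.36 to −0.18), at percentile 0.02 of 10000 matched random lists, with 8 of 33 measured members at least 1.5-fold lower and 2 higher. Mecom, a transcription factor that stem cells need, stood at 134 CPM in the knockout and 271 CPM in the wild-type library, a log2 ratio of −1.02 (−1.07 to −0.97). The transcription factor gene Nkx2-3 was lower at −1.15 (−1.43 to −0.88), and Procr, a surface protein of stem cells, at −0.68 (−0.95 to −0.41). Erythroid genes were higher, with a list median of 0.57 (0.51 to 0.62) and 12 of 26 members at least 1.5-fold higher and 0 lower. Among them were Klf1, a regulator of globin genes, at 34.4 and 17.0 CPM, a log2 ratio of 1.02 (0.88 to 1.15), Cldn13 at 0.99 (0.84 to 1.15) and Rhd, a red cell membrane protein, at 0.81 (0.70 to 0.93).

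Megakaryocyte and platelet genes did not stand apart in fetal liver, with a list median of −0.03 (−0.05 to 0.10) at percentile 56.5. Socs2, a feedback inhibitor of cytokine signals, was lower at −0.50 (−0.74 to −0.25). Immediate early and stress genes were higher, with a median of 0.33 (0.29 to 0.38) and 3 of 29 members at least 1.5-fold higher, such as Ier2 at 0.76 and Egr1 at 0.73. An unnamed cluster with Ier2 and Egr1 among its top genes held 1.72% of wild-type and 8.43% of knockout cells. Interferon response genes were higher by a median of 0.16 (0.12 to 0.21), with Ifi27 at 1.08 (0.94 to 1.23) and Isg15 at 0.77 (0.46 to 1.07). This list median was −0.01 with the limit of 10% mitochondrial UMIs. Basophil, mast cell and eosinophil genes had a median of 0.36 (0.19 to 0.56), with Prg2, a granule protein, at 1.17 (0.85 to 1.51). Neutrophil and monocyte genes had a median of 0.23 (0.19 to 0.26), with 0 of 26 members at least 1.5-fold higher or lower, Ctsg at 0.49 and Ccr2 at −0.50.

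Among metabolic and housekeeping lists in fetal liver, oxidative phosphorylation genes had a median log2 ratio of 0.28 (0.26 to 0.29), ribosomal protein genes 0.21 (0.20 to 0.22) and DNA synthesis genes 0.09 (0.05 to 0.12), and these 3 lists stood apart from random lists, with 0 of 43, 0 of 38 and 0 of 44 members at least 1.5-fold higher or lower. Lists that did not stand apart were lymphoid priming at −0.06, mitosis at −0.06, the fetal stem cell programme at −0.17, mitochondrial regulation at 0.01, glycolysis and hypoxia at −0.08, the p53 response at −0.07, non-homologous end joining at −0.13 and nuclear retained RNA at −0.05. The oxidative phosphorylation genes Ndufa1 and Ndufa5 were among the top genes of an unnamed cluster of shallow cells. It held 1.44% of wild-type and 19.8% of knockout cells, the latter at 0.626 of that library's median depth. Its part in the list median was not tested. Egln3, an oxygen sensor that opposes the hypoxia response, was lower at −0.89 (−1.01 to −0.77). The metal-binding proteins Mt2 and Mt1 were higher at 1.23 (1.15 to 1.32) and 1.07 (1.02 to 1.12). Plxdc2 was lower at −1.51 (−1.61 to −1.41) and the cation channel Trpc6 at −0.75 (−0.90 to −0.59). Trpc6 was a top gene of the cluster named stem cell-like, with 15.4% of wild-type and 2.91% of knockout cells.

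Signals from other cells also differed between the fetal liver libraries. Hepatocyte markers had a median log2 ratio of 2.83 (2.52 to 3.10), and albumin (Alb) stood at 35.8 CPM in the knockout and 2.52 CPM in the wild-type library. Globins had a median of 0.65 (0.63 to 0.68), and mitochondrial genes −0.25 (−0.28 to −0.24). The embryonic globin Hbb-y was higher at 3.26 (3.01 to 3.52), and this turned to −0.95 with all barcodes. Macrophage and dendritic markers had a median of −0.26 and stromal markers −0.68, which turned to 0.32 and 0.19 without the clusters of mature, macrophage, hepatocyte, endothelial and stromal cells. B lineage markers at −0.05, T, NK and innate lymphoid markers at −0.11 and endothelial markers at −0.12 did not stand apart. The sex-linked list had a median of −7.85 (−8.64 to −7.20). The stem cell list median was −0.43 with equal weight for every cell, −0.43 with thinned cells and −0.74 with the limit of 10% mitochondrial UMIs.

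**Figure D1:**
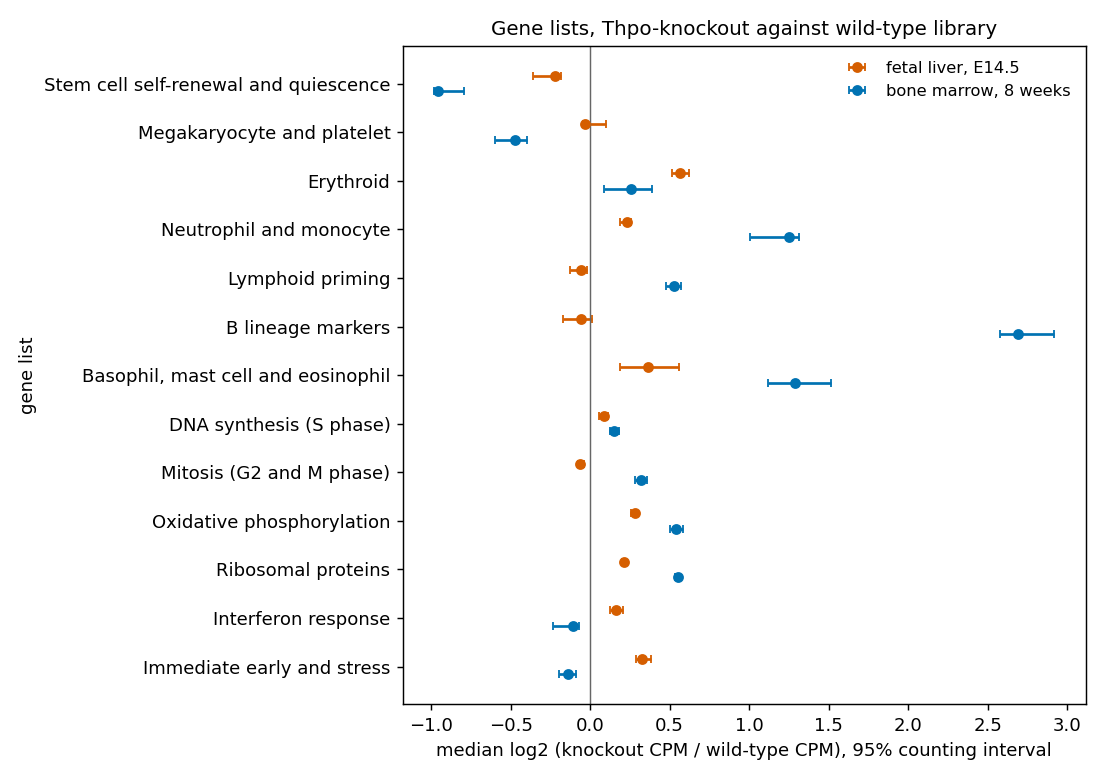
Median log2 ratio of CPM, knockout over wild type, for the gene lists in fetal liver and bone marrow, with 95% intervals for counting error. The stem cell list lies at −0.22 in fetal liver and at −0.95 in bone marrow.

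Stem cell-like cells were fewer in the knockout fetal liver library. They made up 15.4% (14.3 to 16.5) of wild-type cells and 2.91% (2.62 to 3.22) of knockout cells, or 672 and 358 cells. Among cells with at least 2500 UMIs, where the libraries are closer in depth, the shares were 15.8% and 7.69%, and 15.6% and 7.71% when the clusters were also made without stem cell genes. Under the limit of 10% mitochondrial UMIs they were 27.2% and 2.91%. Erythroid progenitor-like cells made up 6.64% of wild-type and 11.2% of knockout cells, and 6.57% and 11.5% of those with at least 2500 UMIs. The class sits in different clusters per library: 1 of shallow cells, at 0.734 of the knockout median depth, held 0.366% of wild-type and 6.81% of knockout cells, and the shared one 6.27% and 4.42%. With knockout cells placed among wild-type clusters this difference shrank from 4.58 to 0.49 percentage points. Lymphoid-primed progenitor-like cells made up 17.2% of both libraries at that depth, and megakaryocyte progenitor-like cells 3.36% of the wild-type and 3.50% of the knockout library. The main shares of these classes were 9.96% and 5.04%, and 2.34% and 1.12%. Neutrophil-monocyte progenitor-like cells made up 13.1% of wild-type and 8.30% of knockout cells, the other way from the median of their genes. This class too sits in different clusters per library: 1 with Ccr2 and Ly86 held 12.9% and 4.10%, and 1 with Elane and Fcnb 0.183% and 4.20%. Another cluster with Elane and Fcnb among its top genes stayed unnamed and held 5.13% and 2.12%. The direction of this share thus depends on which clusters were named. With at least 2500 UMIs these shares were 12.0% and 11.9%, and at resolution 2 they were 3.34% and 9.94%. Unnamed clusters held 28.5% and 10.3%, 1.44% and 19.8%, 0.343% and 12.6%, 1.72% and 8.43%, 5.13% and 2.12%, and 0.550% and 0.342% of wild-type and knockout cells. The 2 almost wholly from the knockout library hold shallow cells, at 0.626 and 0.565 of its median depth, and are read as part of that library and not as cell types.

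Within the stem cell-like cells of fetal liver, Socs2 was lower in the knockout library. It had 1 UMI in the knockout and 75 UMIs in the wild-type cells, 0.598 and 17.8 CPM, a log2 ratio of −4.90 (−10.22 to −2.37). The other clusterings gave 0 to 3 knockout UMIs against 55 to 98 wild-type UMIs. The kinase gene Pim1 stood at −0.23 (−0.45 to −0.02). Immediate early and stress genes had a median of 0.37 (0.28 to 0.50), with 9 of 26 members at least 1.5-fold higher and 3 lower. The RNA-decay factor Zfp36 was higher at 1.08 (0.91 to 1.26), Ier2 at 0.91 (0.74 to 1.09) and the quiescence-linked factor Klf2 at 0.77 (0.66 to 0.88), whereas the heat shock genes Hspa1b and Hsph1 were lower at −1.26 (−1.40 to −1.12) and −0.87 (−1.08 to −0.67). Interferon response genes had a median of 0.42 (0.27 to 0.49), with 6 of 25 members at least 1.5-fold higher. Ifitm3 and H2-K1, both at 0.44, stayed below that fold. Glycolysis and hypoxia genes had a median of −0.16 (−0.24 to −0.05), with Egln3 at −0.72 and Pgk1 at −0.37. Plxdc2 was lower at −1.43 (−1.70 to −1.17). Globins stood at 0.85 (0.66 to 0.96), with 3 of 4 measured members higher, and mitochondrial genes at −0.26 (−0.29 to −0.24). The stem cell list is not read here, because it shares genes with the markers that name the class.

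The bone marrow comparison asks the same of adult LSK cells at 8 weeks. Stem cell genes were lower in the knockout library: the list had a median log2 ratio of −0.95 (−0.98 to −0.79), at percentile 0.00, with 25 of 33 measured members at least 1.5-fold lower and 0 higher. Tek, the angiopoietin receptor of quiescent stem cells, had a log2 ratio of −1.98 (−2.31 to −1.67). Mmrn1 stood at 10.2 CPM in the knockout and 35.4 CPM in the wild-type library, −1.79 (−1.99 to −1.59), with Fgd5 at −1.47 (−1.75 to −1.20) and the adhesion protein Esam at −1.39 (−1.69 to −1.11). Megakaryocyte and platelet genes were lower as well, with a median of −0.47 (−0.60 to −0.40) and 11 of 24 members at least 1.5-fold lower and 0 higher. Thbs1 (thrombospondin) stood at 1.87 and 28.5 CPM, a log2 ratio of −3.93 (−4.39 to −3.51), and von Willebrand factor (Vwf) at −1.88 (−2.27 to −1.50).

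Neutrophil and monocyte, lymphoid and basophil genes were higher in the knockout bone marrow library. Neutrophil and monocyte genes had a median log2 ratio of 1.25 (1.01 to 1.31), with 20 of 25 members at least 1.5-fold higher and 0 lower, among them the granule proteases Ctsg at 180 and 33.3 CPM, 2.44 (2.33 to 2.55), and Elane at 154 and 35.0 CPM, 2.14 (2.03 to 2.25). B lineage markers had a median of 2.69 (2.58 to 2.92), with 9 of 9 members higher, such as the pre-B cell receptor gene Vpreb3 at 3.71 (3.28 to 4.17) and Cd79a at 3.35 (3.02 to 3.71). Lymphoid priming genes had a median of 0.53 (0.48 to 0.57), with the immunoglobulin gene Ighm at 1168 and 181 CPM, 2.69 (2.65 to 2.74), and the B cell factor Ebf1 at 2.64 (2.53 to 2.75). Ighm was a top gene of an unnamed cluster with plasma cell genes, with 0.217% of wild-type and 1.07% of knockout cells. Ebf1 was a top gene of a B lineage-like cluster, with 0.362% and 2.91%. These 2 ratios are thus not read as priming of progenitors. Basophil, mast cell and eosinophil genes had a median of 1.29 (1.12 to 1.52), with the protease Mcpt8 at 1.29 (1.02 to 1.57). Macrophage and dendritic markers had a median of 1.72 over 5 measured members. Erythroid genes had a median of 0.26 (0.09 to 0.39), with 3 of 21 members at least 1.5-fold higher and 2 lower, which turned to −0.03 with thinned cells, and T, NK and innate lymphoid markers 0.57, which turned to −0.41 with a floor of 500 UMIs.

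Cish, a feedback inhibitor of cytokine signals, was lower in the knockout bone marrow library at 3.46 and 7.26 CPM, a log2 ratio of −1.07 (−1.45 to −0.69). The kinase gene Pim1 stood at 337 and 599 CPM, −0.83 (−0.87 to −0.79), and Socs2 at −0.58 (−1.01 to −0.17). Aass, an enzyme of lysine breakdown, was among the single genes with low ratios, with 1 UMI against 2239 UMIs. Its log2 ratio was −11.18 (−16.49 to −8.70). Others were B3galt1 at −3.65 (−4.05 to −3.28), Trpc6 at −3.08 (−3.23 to −2.93) and Plxdc2 at −2.44 (−2.59 to −2.30). B3galt1 was a top gene of the cluster named stem cell-like, with 21.1% of wild-type and 1.74% of knockout cells. Its ratio is therefore not separate from that share. The immunoglobulin gene Ighg2c had 957 UMIs against 2 UMIs, a log2 ratio of 8.85 (6.99 to 11.90).

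In the knockout bone marrow library, medians were 0.54 (0.50 to 0.59) for oxidative phosphorylation and 0.55 (0.54 to 0.56) for ribosomal proteins, where 20 of 43 and 17 of 38 members were at least 1.5-fold higher. Lists that follow RNA quality differed in this pair too, with nuclear retained RNA at −0.60 and mitochondrial genes at −0.35 (−0.36 to −0.34), and the rRNA-linked genes Gm42418 and AY036118 made up 4.76% of wild-type and 2.99% of knockout UMIs. Mitosis genes had a median of 0.32 (0.28 to 0.36), with Ube2c at 0.90 (0.78 to 1.02), and DNA synthesis genes 0.15 (0.12 to 0.18), with 2 of 44 members at least 1.5-fold higher, which turned to −0.17 with the limit of 10% mitochondrial UMIs. Immediate early and stress genes had a median of −0.14 (−0.20 to −0.09), with Egr1 at −1.11 (−1.18 to −1.05), and that median was 0.00 under the same limit. Interferon response genes had a median of −0.11 (−0.23 to −0.07), with Rsad2 at −0.98 and Bst2 at 0.78. The fetal stem cell programme had a median of −0.53 (−0.92 to −0.20) over 9 measured members, with Grb10 at −1.79 and Hmga2 at 0.83. Mitochondrial regulation at −0.09, glycolysis and hypoxia at 0.15, the p53 response at 0.08, non-homologous end joining at 0.08, endothelial markers at 0.13, hepatocyte markers at −0.39, stromal markers at −0.75 and sex-linked genes at 0.23 did not stand apart. Globins had a median of 1.33. With the limit of 10% mitochondrial UMIs, which keeps 209 wild-type and 591 knockout cells, the stem cell list median was −0.64 and that of megakaryocyte and platelet genes −0.19. The stem cell median was thus lower in bone marrow than in fetal liver in the main analysis, and the order turned under this limit, with −0.74 in fetal liver.

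Stem cell-like cells made up 21.1% (20.2 to 22.0) of the wild-type and 1.74% (1.44 to 2.09) of the knockout bone marrow library, or 1748 and 112 cells. These cells were shallow, at 0.815 of the wild-type and 0.621 of the knockout median depth. Among cells with at least 2500 UMIs the class held 441 wild-type and 29 knockout cells. The part of depth and RNA quality in this share was not tested. Unnamed clusters also carried stem cell markers: 1 with Hlf, Mecom, Procr and Robo4 held more of the knockout (15.1%) than of the wild-type library (12.8%), and 1 with Mecom, Fgd5, Tek and Esam held 6.78% and 17.1%. With the stem cell-like class, a sum chosen after the values were seen, these clusters held 51.0% of wild-type and 23.6% of knockout cells. The border of this class moved with the clustering: the shares were 13.9% and 1.20% with doublets kept, 10.9% and 0.778% without stem cell genes, 9.88% and 0.467% with knockout cells placed among wild-type clusters, and 21.2% and 6.77% at resolution 0.5. Among cells with at least 2500 UMIs and without stem cell genes the difference was −10.2 percentage points. Lymphoid-primed progenitor-like cells made up 6.96% and 20.4% of wild-type and knockout cells, and neutrophil-monocyte progenitor-like cells 5.52% and 17.2%. These shares moved with the clustering: the lymphoid-primed ones were 10.6% and 14.9% at resolution 2, and the neutrophil-monocyte ones 1.81% and 6.86% at resolution 0.5 and 2.13% and 6.89% with thinned cells. With all 4 libraries clustered together only 2 wild-type and 6 knockout bone marrow cells fell in the neutrophil-monocyte class, so that clustering is no check of it. B lineage-like cells made up 0.435% and 3.53%, and megakaryocyte progenitor-like cells 5.39% and 3.77%. Other unnamed clusters held 15.1% and 8.98%, 4.26% and 14.1%, 7.57% and 1.32%, 0.604% and 1.57%, 0.217% and 1.07%, 0.809% and 0.265%, and 0.157% and 0.669% of wild-type and knockout cells.

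**Figure D2:**
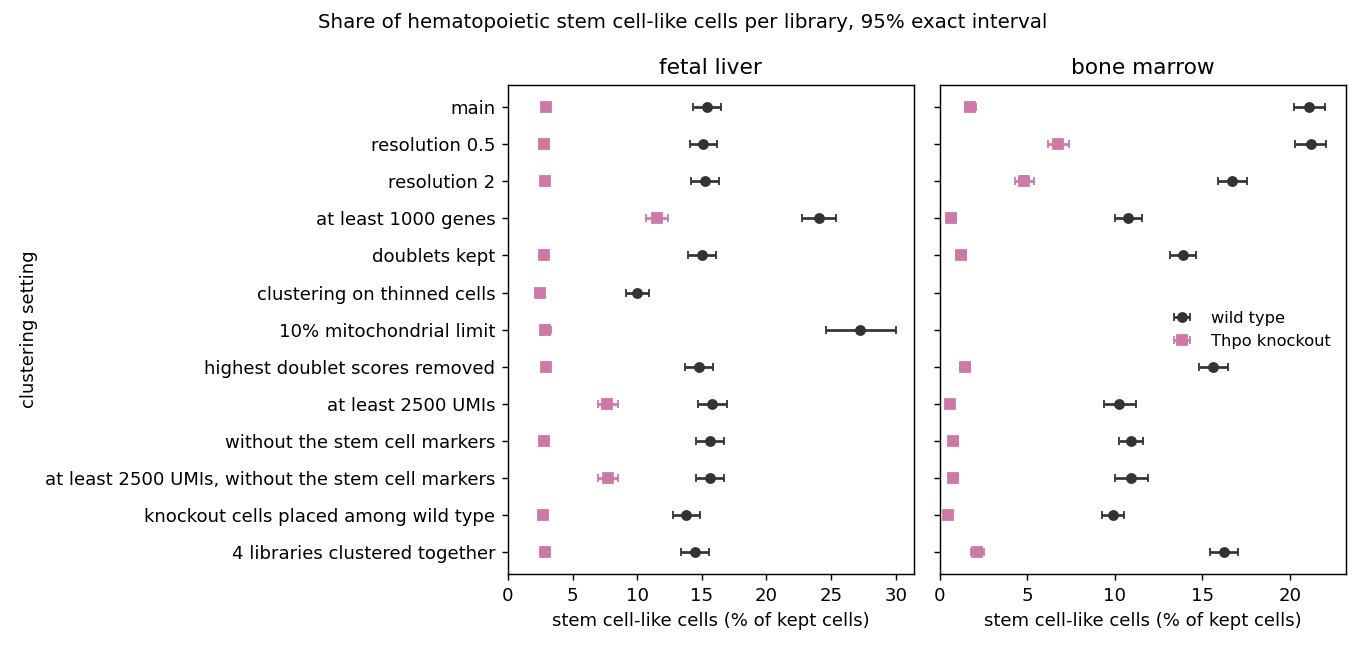
Share of cells in percent named stem cell-like in each library, per clustering setting, for fetal liver and bone marrow. The main shares are 15.4% and 2.91% in wild-type and knockout fetal liver, and 21.1% and 1.74% in wild-type and knockout bone marrow.

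Within the stem cell-like cells of bone marrow, Socs2 had 0 UMIs in the 112 knockout cells and 65 UMIs in the 1748 wild-type cells, so it was at least 1.38-fold lower against a floor of 3 counts. At resolution 0.5 the counts were 1 and 64 UMIs. Pim1 stood at −0.40 (−0.64 to −0.16). DNA synthesis genes had a median of −0.72 (−0.88 to −0.41), with 6 of 40 members at least 1.5-fold lower, such as the helicase subunit Mcm5 at −1.76 (−3.39 to −0.52). That median was −0.12 at resolution 0.5 and −0.22 at resolution 2. Neutrophil and monocyte genes, which mark another cell type, were higher in these knockout cells at 0.81 (0.34 to 1.09), with 5 of 9 members at least 1.5-fold higher. Thbs1 was lower at −2.97 (−6.02 to −1.10) and Plxdc2 at −2.15 (−2.99 to −1.42). Ribosomal protein genes had a median of 0.47 (0.43 to 0.52) and mitochondrial genes −0.56 (−0.61 to −0.53).

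The wild-type stage comparison asks how fetal liver and adult LSK cells differ when thrombopoietin is present. Its libraries also differ in sex, male in fetal liver and female in bone marrow. The median gene was higher in the fetal liver library by 0.24 on the log2 scale, and the values here are relative to it, while counts of members are taken before that shift. The fetal stem cell programme stood at 4.69 (4.55 to 5.43), with 17 of 18 measured members at least 1.5-fold higher and 0 lower. Igf2bp1 (135 and 0.0404 CPM) and Igf2bp3, RNA-binding proteins of the fetal programme, were higher at 11.46 (8.98 to 16.77) and 7.54 (7.01 to 8.12). The imprinted H19 had 0 UMIs in bone marrow and stood at 7.92 or more against a floor of 3 counts. Interferon response genes were lower in fetal liver at −1.64 (−1.76 to −1.54), with 30 of 35 members at least 1.5-fold lower and 1 higher, such as Ifi44 at −6.56 and the histocompatibility gene H2-K1 at −3.67. The stem cell list stood at −1.04 (−1.30 to −0.98), with 17 members lower and 6 higher. Cdkn1c, a cell cycle inhibitor, was higher at 2.42, whereas Ndrg1 and Nr4a1 were lower at −3.58 and −3.57.

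Relative to the median gene, erythroid genes of wild-type fetal liver stood at 2.35 (2.23 to 2.46), globins at 7.23, neutrophil and monocyte genes at 1.58 (1.48 to 1.66), B lineage markers at 3.41 (3.13 to 3.63), oxidative phosphorylation at 1.31 (1.24 to 1.34), mitosis at 0.55 (0.50 to 0.59) and DNA synthesis at 0.29 (0.26 to 0.33). Megakaryocyte and platelet genes stood at −0.60 (−0.66 to −0.53), and lymphoid priming, which did not stand apart, at −0.21, where Dntt, the enzyme that adds nucleotides to antigen receptor genes, was lower at −8.40 (−9.13 to −7.75) and the recombinase Rag1 higher at 3.67. Cish stood at −2.83 (−3.34 to −2.36), Pim1 at −2.41 (−2.46 to −2.37) and the heat shock gene Hspa1a at 4.57 (4.46 to 4.69). Endothelial markers stood at 5.27 (4.78 to 5.72) and macrophage and dendritic markers at 4.80 (4.18 to 5.25). Hepatocyte markers stood at 2.10 (1.83 to 2.33), but their median before the shift turned from 2.34 to −0.42 with thinned cells. Lists that follow RNA quality differed too, with mitochondrial genes at −1.04 (−1.04 to −1.03), nuclear retained RNA at −0.89 (−0.90 to −0.88) and ribosomal proteins at 0.50 (0.49 to 0.51). RNA of the rRNA-linked genes Gm42418 and AY036118 made up 0.62% of UMIs in wild-type fetal liver and 4.76% in wild-type bone marrow.

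In the knockout libraries, both female, the median gene was higher in fetal liver by 0.18. Relative to it the fetal stem cell programme stood at 5.88 (5.42 to 6.14) and interferon response genes at −1.40 (−1.46 to −1.31). Stem cell genes stood at −0.54 (−0.72 to −0.48), and B lineage markers at 0.45 (0.36 to 0.52), which did not stand apart. Immediate early and stress genes stood at 0.32 (0.26 to 0.39). Megakaryocyte and platelet genes stood at 0.43 (0.13 to 0.56), but their median before the shift turned from 0.61 to −0.27 with thinned cells. Markers of other cells stood at 3.88 (3.69 to 4.16) for hepatocyte, 5.11 (4.63 to 5.58) for endothelial and 2.45 (2.10 to 2.90) for macrophage and dendritic lists. Mitochondrial genes stood at −0.92 (−0.93 to −0.92), and their median before the shift turned from −0.74 to 0.04 with the limit of 10% mitochondrial UMIs. The rRNA-linked genes made up 0.53% of UMIs in knockout fetal liver and 2.99% in knockout bone marrow.

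**Figure D3:**
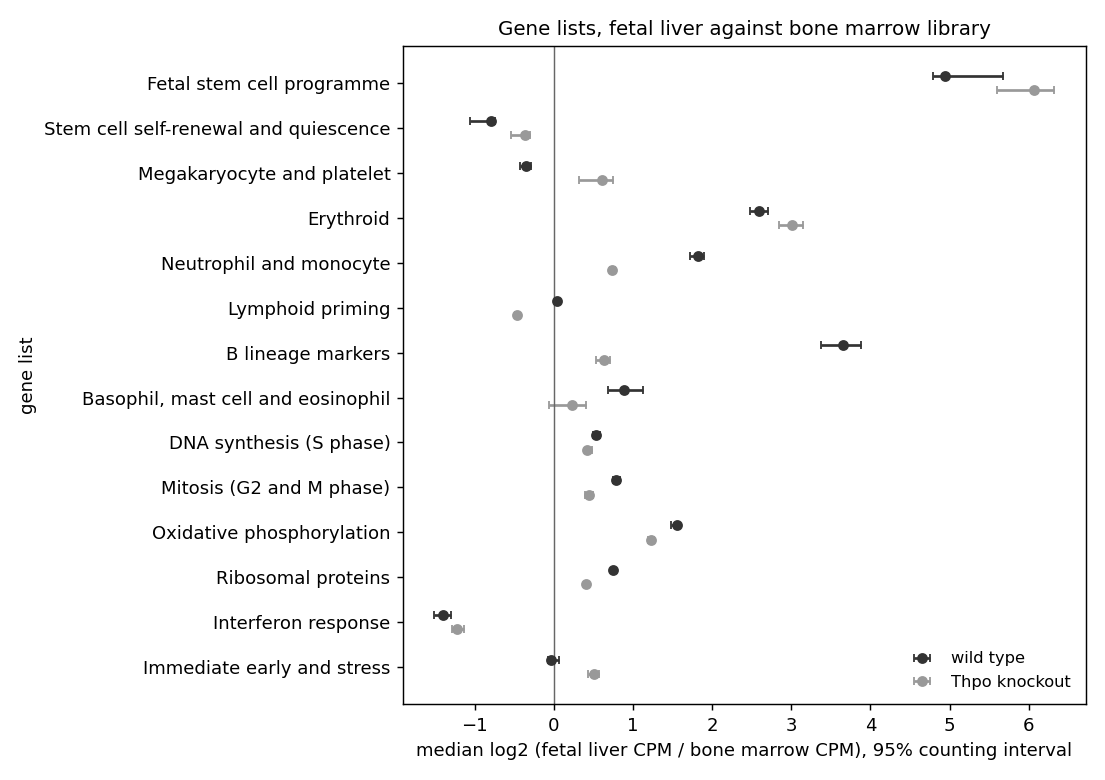
Median log2 ratio of CPM, fetal liver over bone marrow, for the gene lists in the wild-type and knockout libraries, with 95% intervals for counting error. Before the shift by the median gene, the fetal stem cell programme lies at 4.93 in the wild-type and at 6.07 in the knockout libraries.

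At a matched depth of 500 UMIs per cell, Mecom was found in 11.2% of wild-type and 6.12% of knockout fetal liver cells, and in 23.4% and 11.7% of wild-type and knockout bone marrow cells. Without thinning these shares were 37.0%, 16.7%, 61.8% and 44.7%. In B lineage-like cells, which should lack Mecom, the thinned shares were 0%, 1.52%, 2.78% and 1.32%, at median depths of 7411, 1746, 2179 and 2467 UMIs against library medians of 7705, 1518, 2559 and 3538 UMIs. Mpo, a neutrophil granule enzyme, was found in 19.1%, 30.8%, 11.6% and 18.1% of cells in the same order, and in 3.97%, 21.1%, 5.56% and 5.29% of B lineage-like cells. In T and NK-like cells its shares were 11.8%, 15.1%, 5.19% and 7.92%. Without thinning its shares were 69.3%, 62.6%, 38.1% and 52.6%. The B lineage-like class of fetal liver sits in 2 clusters: 1 of shallow cells with 3 wild-type and 346 knockout cells, and 1 with 224 and 179. Free RNA, remaining doublets and misplaced cells were not separated as sources of Mpo in B lineage-like cells of the knockout fetal liver library. Cells scored as G1 made up 18.6%, 14.2%, 36.4% and 31.4% of the libraries at that depth, but 34.3% of both bone marrow libraries with cells thinned to 2000 UMIs. This is read only beside the lists of DNA synthesis and mitosis.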

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

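The tests of a difference in sex and all tests of passenger sequence around Thpo were chosen only after the results were seen. The differences between stages given last were not tested.

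Stem cell genes were lower in the knockout bone marrow library, with a list median log2 ratio of −0.95. Dilution by other cell types in the sort was examined by leaving out clusters with 8.09% of wild-type and 25.3% of knockout cells. The median was then −0.77 (−0.84 to −0.70), so these clusters account for part of it at most. Dilution as such is not decided, because the cells left out are too few to bring the median back to no difference. Lymphoid-primed cells and the unnamed clusters, except that of plasma cells, stayed in. Mitochondrial and other abundant RNA in the totals is argued against, since the median was −1.05 (−1.08 to −0.89) with totals that leave it out. A different mix of clusters was examined with clusters made without stem cell genes. Against counts expected from wild-type rates per cluster, the median was −0.14 (−0.23 to −0.12), between the bounds set for and against it. This is much closer to no difference than the unmatched −0.95. Much of the lower median thus went with the cluster that cells fell in, and the remainder stays open. Only the stem cell markers and list genes were left out of the clustering. Cells with lower stem cell genes may differ in other genes too and fall in other clusters. Matching by cluster therefore does not separate a different mix from a lower level per cell. The loss of Thpo may act through fewer stem cells or through lower genes per cell, and the data do not settle the part of each.

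Stem cell genes were also lower in the knockout fetal liver library, with a list median of −0.22. Shallow barcodes with free RNA are argued against, since the median was −0.27 (−0.35 to −0.19) in cells with at least 2500 UMIs. A difference in sex between the libraries cannot be told apart from genotype, because there are 0 pairs of male and female libraries of 1 genotype and stage. A different mix of clusters stays open, with a median of −0.089 (−0.124 to −0.012) against counts expected from wild-type rates per cluster. This was in cells with at least 2500 UMIs and is closer to no difference than the unmatched −0.27. The loss of Thpo remains a possible explanation beside these.

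The 5 genes Slc15a2, Aass, Gm47283, Ighg2c and Ighg2b, chosen after their values were seen, were on in 1 library and nearly off in the other library of its stage. The median observed over expected count in the lower library, from rates per cluster, was 0.0069 (0.0000 to 0.0098). A different mix of clusters is argued against for Slc15a2, Aass and Gm47283, at 0.0000, 0.0003 and 0.0069. It is not decided for Ighg2c and Ighg2b, at 0.0328 and 0.0715. The bone marrow cluster with plasma cell genes held 18 wild-type cells, under the 20 cells per library needed, and was left out. Passenger sequence around the targeted Thpo gene is argued against as the cause for all of these genes, since 4 of them lie on other chromosomes and 1, Slc15a2, within 20 Mb of Thpo. For Slc15a2, with 0 UMIs in wild-type and 340 UMIs in knockout fetal liver, passenger sequence that acts in both stages is argued against as well: in bone marrow its knockout log2 ratio was −0.57 (−0.74 to −0.41), at 19.1 CPM against 28.5 CPM. Passenger sequence acting on Slc15a2 in fetal liver alone stays open, and no strain difference or biological explanation was tested.

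Some knockout ratios had opposite signs in fetal liver and bone marrow, and these differences were not tested. As bone marrow minus fetal liver, the B and T cell factor Lef1 stood at 3.52 (−0.61 in fetal liver and 2.91 in bone marrow) and Ebf1 at 3.07 (−0.43 and 2.64). The monocyte genes F13a1, Ly86 and Mpeg1 stood at 2.47 (−0.31 and 2.16), 2.29 (−0.36 and 1.93) and 1.81 (−0.36 and 1.45). Sox6, a factor of red cell and megakaryocyte precursors, stood at −2.08 (0.19 and −1.89), and Car2 at −1.45 (0.28 and −1.18). The immediate early genes Egr1 and Ier2 stood at −1.84 (0.73 and −1.11) and −1.32 (0.76 and −0.56). Median differences were 0.62 for lymphoid priming, 0.36 for mitosis, −0.28 for interferon response, 0.26 for glycolysis and hypoxia and −0.47 for immediate early and stress genes. They were 1.60 for macrophage and dendritic and −0.43 for hepatocyte markers, over 4 and 3 members measured in both tissues, whose fetal liver medians were −0.03 and 0.40. Alternatives ended the opposite signs for some lists. The fetal liver median of macrophage markers was 0.32 without mature, macrophage, hepatocyte, endothelial and stromal clusters. With the limit of 10% mitochondrial UMIs it was 0.22 for lymphoid priming, 0.011 for mitosis and −0.011 for interferon response, and the bone marrow median was 0.0030 for immediate early genes and 0.65 for hepatocyte markers.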

How the results depend on the processing

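The limit of 10% mitochondrial UMIs as an alternative, at least 2500 UMIs, removal of the highest doublet scores, clustering without stem cell genes and thinning to 2000 UMIs were tried only after the data were seen. Of 1796 alternative values over 156 list medians, 1218 stayed within the main interval and 17, from 11 of these medians, reversed a main change. A change here is a main interval without 0, for lists also a median outside the range of random lists, and for genes also a ratio of at least 1.5-fold. Of 5513 values over 553 gene ratios, these were 4305 and 12, of 200 over 19 class shares 91 and 31, of 78 over 26 shares of cells with a UMI 25 and 3, and of 12 over 6 phase shares 3 and 0. The stem cell list median kept its sign in 14 alternatives, from −0.74 to −0.18 in fetal liver and from −1.05 to −0.64 in bone marrow. The fetal programme in wild type ranged from 3.66 to 5.68, before the shift of the median gene. The difference in the stem cell-like share ranged from −24.3 to −7.56 percentage points over 12 alternatives in fetal liver. In bone marrow it ranged from −14.4 to −9.41 over 10 alternatives, all smaller than the main −19.4, so that main value is at the far end. In bone marrow no cluster was named stem cell-like with clustering on thinned cells or under the limit of 10% mitochondrial UMIs. Ratios within that class have no value there, nor under 5 settings with fewer than 100 knockout cells. Depth limits the shares in knockout fetal liver, where 62.4% of cells hold fewer than 2500 UMIs. Counting values without such a change as well, the main sign was kept by 1654 alternative values of list medians and 5428 of gene ratios. It was also kept by 169 values of class shares, 65 of shares of cells with a UMI and 10 of phase shares. Outside the main interval without a reversed change were 561 alternative values of list medians and 1196 of gene ratios. So were 78 values of class shares, 50 of shares of cells with a UMI and 9 of phase shares. The values below are those that reversed a main change and, for the stem cell list in knockout against wild type, the fetal programme in wild type and the stem cell-like share, also those outside the main interval. The main differences of the class shares that reversed were, in fetal liver, B lineage −0.928, endothelial 1.92, lymphoid-primed −4.92, macrophage 1.88, megakaryocyte progenitor −1.21, neutrophil-monocyte −4.80 and T and NK −0.441, and in bone marrow basophil 0.481, erythroid 0.432 and megakaryocyte progenitor −1.62. The values below are log2 values, or percentage points for shares, and the cause was not tested.

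With the limit of 10% mitochondrial UMIs, the stage ratio in wild type was Afp −0.23, fetal programme 3.66 and hepatocyte markers −0.37, and the class share in fetal liver differed by B lineage 1.88, endothelial −11.7, stem cell-like −24.3, macrophage −1.35 and neutrophil-monocyte 5.21. Then the knockout ratio in bone marrow was Car1 −0.090, DNA synthesis −0.17, Gata3 0.32, Gins2 −0.67, immediate early 0.0030, Sesn2 0.59 and stem cell list −0.64, and the knockout ratio in fetal liver was interferon −0.011 and stem cell list −0.74. Then the stage ratio in knockout was mitochondrial genes 0.042. With all 4 libraries clustered together, the class share in bone marrow differed by basophil −0.872, stem cell-like −14.1 and megakaryocyte progenitor 0.042, and the class share in fetal liver differed by macrophage −0.552. With TMM scaling, the stage ratio in wild type was fetal programme 4.71, and the knockout ratio in fetal liver was stem cell list −0.18. With all barcodes, the knockout ratio in fetal liver was Hbb-y −0.95. With at least 1000 genes, the class share in fetal liver differed by endothelial −2.13, macrophage −0.577, neutrophil-monocyte 3.93 and T and NK 0.277, and the stage ratio in wild type was fetal programme 4.76. Then the class share in bone marrow differed by stem cell-like −10.1. With at least 2500 UMIs, the class share in fetal liver differed by endothelial −0.018, stem cell-like −8.12, lymphoid-primed 0.055, macrophage −0.527 and megakaryocyte progenitor 0.143, and the class share in bone marrow differed by stem cell-like −9.67. With that depth and clusters made without stem cell genes, the class share in fetal liver differed by endothelial −0.039, stem cell-like −7.89, lymphoid-primed 0.270, macrophage −0.527, megakaryocyte progenitor 0.195 and T and NK 0.481, and the class share in bone marrow differed by stem cell-like −10.2. With clustering on thinned cells, the class share in bone marrow differed by erythroid progenitor −0.956, and the class share in fetal liver differed by stem cell-like −7.56, macrophage −0.670 and neutrophil-monocyte 2.31. With doublets kept, the class share in bone marrow differed by stem cell-like −12.7. With a floor of 500 UMIs, the stage ratio in wild type was fetal programme 5.68 and hepatocyte markers −0.72, and the stage ratio in knockout was megakaryocyte list −0.34. Then the knockout ratio in bone marrow was stem cell list −0.77 and T and NK markers −0.41, and the knockout ratio in fetal liver was stromal markers 0.20. With the highest doublet scores removed, the class share in bone marrow differed by stem cell-like −14.2, and the class share in fetal liver differed by neutrophil-monocyte 2.54. With knockout cells placed among wild-type clusters, the class share in fetal liver differed by endothelial −3.43, stem cell-like −11.1 and macrophage −1.19, and the class share in bone marrow differed by stem cell-like −9.41. With equal weight for every cell, the knockout ratio in fetal liver was stem cell list −0.43. With DESeq2 size factors, the stage ratio in wild type was fetal programme 4.69, and the knockout ratio in bone marrow was stem cell list −0.98. Then the knockout ratio in fetal liver was stem cell list −0.18. Without thinning, the difference in cells with a UMI in fetal liver was Gata1 −1.28, Mpo −6.78 and Pf4 −3.23. At resolution 0.5, the class share in bone marrow differed by erythroid progenitor −0.627 and stem cell-like −14.4, and the class share in fetal liver differed by macrophage −0.619. Then the ratio in stem cell-like bone marrow cells was Mcm2 0.078. At resolution 2, the class share in bone marrow differed by stem cell-like −11.9, and the class share in fetal liver differed by macrophage −0.536 and neutrophil-monocyte 6.60. Then the ratio in stem cell-like bone marrow cells was Mcm2 0.13. With thinned cells, the knockout ratio in bone marrow was erythroid list −0.030 and T and NK markers −0.25, and the stage ratio in wild type was hepatocyte markers −0.42. Then the stage ratio in knockout was megakaryocyte list −0.27, and the knockout ratio in fetal liver was stem cell list −0.43. With totals without the most abundant genes, the stage ratio in wild type was fetal programme 4.72, and the knockout ratio in bone marrow was stem cell list −1.05. Without mature, macrophage, hepatocyte, endothelial and stromal clusters, the stage ratio in wild type was Afp −0.086 and hepatocyte markers −0.51, and the knockout ratio in fetal liver was C1qa 1.34, C1qc 0.86, Cd5l 0.53, macrophage markers 0.32 and stromal markers 0.19. Then the stage ratio in knockout was T and NK markers 0.12. With clusters made without stem cell genes, the class share in bone marrow differed by stem cell-like −10.1, and the class share in fetal liver differed by macrophage −0.561.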

Other observations

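The values here were chosen after they were seen. The lysine enzyme gene Aass stood at 2.17, 1.07, 90.4 and 0.0389 CPM in the wild-type fetal liver, knockout fetal liver, wild-type bone marrow and knockout bone marrow libraries. The gene model Gm47283, annotated on the Y chromosome, stood at 22.8, 181, 112 and 0.856 CPM in the same order. This does not follow Ddx3y, Eif2s3y, Kdm5d and Uty, and the gene model was not used to tell the sex of the libraries. Slc15a2, a peptide transporter, stood at 0, 8.30, 28.5 and 19.1 CPM. The immunoglobulin genes Ighg2c and Ighg2b stood at 0 and 2.20 CPM in wild-type fetal liver, 0 and 3.64 in knockout fetal liver, 0.0807 and 0.363 in wild-type bone marrow, and 37.2 and 29.1 in knockout bone marrow. An unnamed bone marrow cluster with plasma cell genes held 0.217% of wild-type and 1.07% of knockout cells.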
